A study of Mus musculus with 6 samples.

How the data were processed

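The samples were 6 poly(A) RNA-seq libraries of mouse iPSC lines, 3 miR-34a knockout and 3 wild-type, grouped by the genotype and replicate number in the labels. The labels describe the libraries as strand-specific and the lines as independent. The deposited table holds raw counts per feature for each library, not normalized, per the labels and the values, which are whole numbers. The submitters' processing notes name TopHat2 2.0.11, featureCounts 1.4.5 and the mm10 build. The counting options, including strand and the handling of reads that map to several places, are not given in the sources used here. The table has 42290 rows, of which 41388 are Ensembl gene identifiers and 902 are repeat families. A further table from a repeat sequencing run has 6 columns whose names match no label, and these 6 columns were not used in any step. The plan fixed before the data were examined was to add both runs per sample, and the results here rest on the first table alone.

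Gene symbols came from a GENCODE M21 name table, which matched 40254 of the 41388 identifiers, and coordinates from the M21 annotation of the same build. Of 540 genes in 22 lists fixed before the data were examined, 535 were matched. The lists covered 2-cell stage genes, MERVL-driven chimeric transcript genes, pluripotency, primed epiblast, germline, primitive endoderm, trophoblast, gastrulation and mesoderm, neural, fibroblast, p53 target, reported miR-34a target, GATA2 target and GATA-associated, hypoxia and glycolysis, interferon response, histone, mitochondrially encoded, retroviral silencing and chromatin repressor, Dlk1-Dio3 imprinted, other imprinted and sex-linked genes, and the targeted gene with its family. The last was not tested as a list because its 3 members were not past the count filter.

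Depth ranged from 8432597 to 29654855 counts per library. In the shallowest library, 3 gene counts correspond to 0.378 CPM, so differences among genes near or under that level were not resolved there. Intervals on counts are exact (Clopper-Pearson) at 95%, floors are 3 counts over a group, and both cover counting error only. Before libraries were averaged, pairs were compared by chi-square over genes with at least 20 counts in the pair. The P values weigh the genotype difference against the spread between the lines of a genotype. Which lines share an embryo or a colony is not given in the sources used here. If lines of a genotype share an origin, that spread does not stand for independent lines.

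Genes were tested with edgeR 4.0.16 in R 4.3.3. Low counts were removed with filterByExpr, libraries were scaled with TMM factors, and the quasi-likelihood F test (glmQLFit with robust = TRUE, glmQLFTest, two-sided) compared knockout with wild-type with no covariate. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Standard errors are the log2 fold change divided by the square root of F. Repeat families were tested in the same way with library sizes and TMM factors of the genes. Lists with at least 3 tested members, 21 in all, were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry, each adjusted over the lists. With an estimated correlation no list passed, the lowest adjusted p being 0.07, while 15 passed with the preset one. With fry, which asks whether the members move one way on balance, 16 passed. Principal components used log2 CPM with a prior count of 2.

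Named genes follow a rule fixed before the data were examined. They are the 10 largest upward and 10 largest downward log2 fold changes among called genes whose groups do not overlap and whose mean is at least 1 CPM, up to 3 members of each list with the smallest p, and Mir34a, Gata2, Zfp352, Tcstv1, Tcstv3, the Zscan4 genes, Pou5f1, Nanog, Sox2, Klf4, Cdx2, Xist and 4 Y-linked genes. Names outside it were chosen after their values were seen.

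GC content and 50-base uniqueness were computed from the annotated transcripts. The steps were tested on simulated counts for 14525 genes with 200 genes changed. Of the changed genes that were tested, 26.5% were recovered at 1.2-fold, 68.8% at 1.5-fold, 88% at 2-fold and 100% at 4-fold, and 7 unchanged genes were called. When a GC trend was added to one group in a simulation of 14504 genes, 208 unchanged genes were called, and 12 were called after library GC trends were removed. Each simulation changed 200 genes, while 50.5% of the tested genes were called in the data. Scaling and p adjustment were thus not tried with so many changes, and these recovery and false-call figures do not carry over to the data.

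The alternatives were DESeq2 size factors in edgeR, library totals only, DESeq2 1.42.0, limma voom, no count filter beyond 1 count, at least 1 CPM in 3 samples, the replicate number as a block, robust = FALSE, each library left out, and the estimated correlation for lists. The test of repeat families, the counts at 2-fold or more and the blocks of the X chromosome were added after the data were seen. Retroviral families were taken by the start of their names, IAP, ETn, MMETn and RLTR, and in a wider set, chosen later, also ERVB, ERVL, RMER, MMERVK, MYSERV, MuRRS, MuLV, MMERGLN, MURVY, MurERV, RodERV, RNERVK, SRV and LTRIS. Alternatives chosen after the data were seen were autosomal genes only, genes and repeat families in 1 fit, offsets with library GC trends removed (lowess, span 0.3), and repeat counts scaled by their own totals.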

Results

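Poly(A) RNA from mouse induced pluripotent stem cells (iPSCs) was sequenced in 6 libraries, 3 from miR-34a knockout lines and 3 from wild-type lines. The labels describe 3 independent lines per genotype, made from embryonic fibroblasts of littermates by retroviral Oct4, Sox2 and Klf4 and grown on irradiated fibroblast feeders. The comparison asks how the transcriptome of pluripotent cells differs when miR-34a, a microRNA induced by p53, is missing. Total counts were 20877988, 29654855 and 8721581 in knockout replicates 1 to 3 and 25698286, 8432597 and 16760545 in wild-type replicates 1 to 3. Of the counts in a library, 5.4% to 6.16% belonged to repeat families and the rest to genes. Levels are CPM (counts scaled to a common library size), given as mean ± SD over n = 3 lines per genotype, and fold changes are log2 of knockout over wild-type with SE.

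The targeted gene gave no check of the labels. Mir34a (ENSMUSG00000065493, a microRNA hairpin gene at chromosome 4, 150068454 to 150068555, mm10) had 1 count in knockout replicate 1, 2 counts in wild-type replicate 1 and 0 in the other libraries. Its paralog Mir34b had 1 count in wild-type replicate 1, and Mir34c had 0 in every library. Both groups were at or under the floor of 3 counts, so no fold was computed, and poly(A) libraries hold few reads of short hairpin genes.

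The genotypes lay apart on the first principal component, which held 79.9% of the variance, with knockout libraries between -46.4 and -43.8 and wild-type libraries between 42.4 and 47.8. The common biological coefficient of variation was 6.3% over both genotypes, 6.9% in the knockout and 5.5% in the wild-type libraries. No pair of libraries agreed within sampling noise, with a chi-square per degree of freedom of 2.25 to 20.01 within and 16.3 to 64.2 between genotypes. This value grows with depth, so the ranges do not compare the sizes of the differences. The 20.01 came from knockout replicates 1 and 2, whose log2 CPM correlated at 0.9971. The 16.3 came from the shallow knockout replicate 3 and wild-type replicate 2, which correlated at 0.9704.

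Gene expression differed between the genotypes across the whole transcriptome, mostly by small folds. Of 14717 genes tested, 3905 were higher and 3528 lower in the knockout at adjusted p under 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg), and the median absolute log2 fold change of the called genes was 0.48. A fold change of at least 2 was reached by 1118 of the higher and 397 of the lower genes. The groups did not overlap in 8248 tested genes (56.0%), where chance gives 10%. The 10 genes with the largest upward fold changes all had 0 counts in the wild-type libraries, so their folds are lower bounds against a floor of 3 counts over the wild-type group. Pramef25 (ENSMUSG00000078511, chromosome 4, 143948580 to 143951016), of the PRAME-like family, reached 6.04 ± 0.391 CPM in the knockout and was at least 96.4-fold higher. Gm21542 was at least 97.5-fold higher at 5.81 ± 1.39 CPM. The steroid sulfate transporter gene Slc10a6 (ENSMUSG00000029321) was at least 65.8-fold higher at 3.91 ± 0.628 CPM. The lower bounds were 80.1-fold for AF067061, 66.6-fold for AA623943, 66.3-fold for ENSMUSG00000087346, 63.2-fold for Gm4340, 61.8-fold for Gm5039, 59.5-fold for BC147527 and 57.8-fold for Gm8994. Pramef25, Gm4340 and Gm8994 are also members of the 2-cell stage list described further on. Of their 50-base stretches only 36.5%, 1.1% and 52.5% were unique among annotated transcripts, so reads may be shared with near-identical copies. Uniqueness was not computed for the rest of the 10. Of the 10 genes with the largest downward fold changes, 5 were Y-linked and 4 belonged to the Dlk1-Dio3 imprinted region, both described further on. Fold changes of autosomal genes above 5 CPM followed the GC content of the transcripts (Spearman's rho 0.34 across 9947 genes, which are not independent replicates), with medians of -0.25 in the lowest and 0.10 in the highest GC decile.

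Genes of the 2-cell embryo were higher in the knockout as a group. All 37 tested members of the 2-cell stage list, of 43 matched, rose, and adjusted over the list alone the count was also 37. The median fitted log2 fold change was 6.61, and 4.61 when the 22 members with 3 or fewer wild-type counts were set to their lower bounds. Those 22 passed the count filter through the knockout libraries alone, so they could only be called higher. Other members low in the wild-type libraries, Tmem92 and Zfp352 among them, also needed the knockout libraries to pass. The count of 37 was thus largely fixed by the filter. Only Calcoco2, Ddit4l and Cyp2b23 had wild-type means of 0.993 CPM or more, and they rose by 1.16, 1.56 and 1.71 on the log2 scale. Tmem92 (ENSMUSG00000075610, chromosome 11, 94777217 to 94782703) rose from 0.111 ± 0.128 to 32.4 ± 1.56 CPM (log2 fold change 8.49, SE 0.230, edgeR adjusted p = 8.1e-16). Usp17lc and Usp17le, members of a multicopy deubiquitinase family, rose by log2 fold changes of 7.05 and 6.47. Zfp352 (ENSMUSG00000070902, chromosome 4, 90218820 to 90225702), a zinc finger gene read from a retroviral promoter in 2-cell embryos, rose from 0.366 ± 0.246 to 5.01 ± 0.236 CPM (log2 fold change 4.04, SE 0.320, edgeR adjusted p = 4.1e-09). All 5 Zscan4 genes tested rose. Zscan4c had 843 counts in the knockout and 2 in the wild-type libraries, a ratio of 361.5 with an exact 95% counting interval of 99.8 to 2990.3, and Zscan4d and Zscan4f rose by 5.90 and 7.90 on the log2 scale. The counting ratios were 290.8 (51.8 to 11518.6) for Zscan4b and 259.9 (46.3 to 10298.9) for Zscan4e. Tcstv1 had 347 counts against 1, a ratio of 297.6 (53.1 to 11789.6), and Tcstv3 had 156 counts against 1, a ratio of 133.8 (23.7 to 5318.7). Many of these genes have near-identical copies that can exchange reads, and only 14.5% of the 50-base stretches of Zscan4c and 55.3% of those of Usp17lc were unique among annotated transcripts, against 98.1% for Tmem92 and 92.9% for Zfp352. The list test gave a camera adjusted p of 2.6e-63 with a preset correlation and an adjusted p = 0.07 with an estimated correlation.

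Genes spliced to or driven by MERVL, the endogenous retrovirus active in 2-cell embryos, moved with them. All 11 tested members of the MERVL-driven list, of 14 matched, rose, also when adjusted over the list alone, with a median log2 fold change of 5.90 (5.40 with 5 members at their bounds). Those 5 also passed the count filter through the knockout libraries alone and could only be called higher. The other members, at wild-type means of 0.533 CPM or less, needed the knockout libraries to pass as well, except P4ha2. P4ha2 rose from 9.40 to 26.5 CPM (log2 fold change 1.51). That all 11 rose was thus largely fixed by the filter. Chit1 (ENSMUSG00000026450, chromosome 1), which encodes chitotriosidase, rose from 0.498 ± 0.184 to 20.7 ± 1.77 CPM (log2 fold change 5.55, SE 0.192, edgeR adjusted p = 3.1e-14). Usp17lb had 762 counts in the knockout and 3 in the wild-type libraries, a ratio of 217.9 (74.3 to 1058.8). This list was recalled from published work on these cells and shares Zscan4c, Zscan4d, Tcstv1, Tcstv3, Zfp352 and other members with the 2-cell stage list, so it is not independent evidence of the direction. Its camera adjusted p was 7.7e-35 with the preset correlation, with adjusted p = 0.07 with an estimated correlation.

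**Figure D1:**
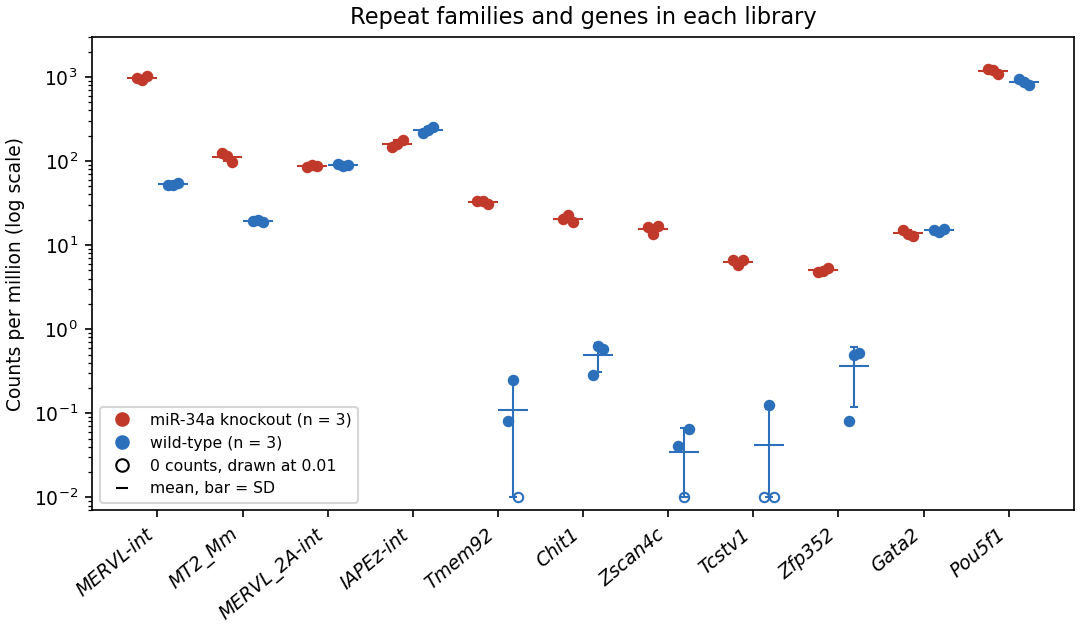
CPM on a log axis for 4 repeat families and 7 genes in each of the 3 knockout (red) and 3 wild-type (blue) libraries. Horizontal marks are means, bars are SD, and open points at 0.01 stand for 0 counts. MERVL-int lay at 977 CPM on average in the knockout and 52.7 CPM in the wild-type libraries, while MERVL_2A-int lay at 86.9 and 89 CPM.

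The MERVL repeats themselves were higher in the knockout. Of 756 repeat families tested, 57 were higher and 73 lower at adjusted p under 0.05, and 13 were higher and 3 lower by at least 2-fold. The families named here were chosen after their values were seen. MERVL-int, the internal part of the retrovirus, rose from 52.7 ± 2.08 to 977 ± 54.3 CPM (log2 fold change 4.21, SE 0.072, edgeR adjusted p = 7.2e-30). Its terminal repeat MT2_Mm rose from 19.4 ± 0.472 to 112 ± 13.2 CPM (log2 fold change 2.54, SE 0.094, edgeR adjusted p = 3.8e-20). The related MERVL_2A-int was at 86.9 ± 2.29 CPM in the knockout and 89 ± 1.96 CPM in the wild-type libraries (log2 fold change -0.03, edgeR adjusted p = 0.8). Other retroviral families went both ways. ERVB4_2-LTR_MM rose from 4.07 ± 1.19 to 32.6 ± 1.65 CPM (log2 fold change 3.01, edgeR adjusted p = 6.9e-17). RLTR45-int and RLTR4_MM-int rose by log2 fold changes of 1.46 and 1.00, while IAPEz-int and MMETn-int fell, with log2 fold changes of -0.54 and -1.25. ETnERV-int had a log2 fold change of -1.01 (edgeR adjusted p = 0.057), and the LINE-1 families L1Md_T and L1Md_A had 0.31 and 0.16 (edgeR adjusted p = 0.44 and 0.22). Which direction held more families depended on the setting, all alternatives being chosen after the data were seen. Higher and lower families numbered 85 and 61 with repeat counts scaled alone, 44 and 26 without knockout replicate 1, 44 and 47 without wild-type replicate 1, and 77 and 110 with genes and families in 1 fit.

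Core pluripotency genes stayed highly expressed in both genotypes and were slightly higher in the knockout. Pou5f1 was at 1180 ± 82 CPM in the knockout and 871 ± 71.8 CPM in the wild-type lines (log2 fold change 0.44, edgeR adjusted p = 2.1e-05), and the log2 fold changes were 0.31 for Nanog, 0.26 for Sox2 and 0.51 for Klf4. Pou5f1, Sox2 and Klf4 are also carried by the reprogramming vectors, and the counts do not separate vector from endogenous transcripts. Of 35 pluripotency genes, 23 rose, 6 fell and 6 were not called. Tcl1, an AKT coactivator, and Zfp57, which protects imprinted methylation, rose by 1.21 and 0.98 on the log2 scale, while Dppa3, a maternal factor also marking germ cells, fell from 91.3 ± 3.59 to 26.3 ± 1.59 CPM (log2 fold change -1.80, SE 0.067, edgeR adjusted p = 7.3e-14). The camera adjusted p was 0.00052, with adjusted p = 0.11 with an estimated correlation. Of 16 primed epiblast genes, 7 fell, 3 rose and 6 were not called (camera adjusted p = 0.00047; adjusted p = 0.077 with an estimated correlation). The de novo DNA methyltransferase gene Dnmt3b fell from 520 ± 26.1 to 168 ± 12 CPM (log2 fold change -1.64, SE 0.061, edgeR adjusted p = 7.3e-14), and the WNT effector Lef1 and the keratin gene Krt18 had log2 fold changes of -1.40 and -1.15. Of 25 germline genes, 17 rose, 2 fell and 6 were not called (camera adjusted p = 0.0081; adjusted p = 0.36 with an estimated correlation). Piwil2 and Rpl10l rose by 0.75 and 0.81, and Prdm1, which encodes BLIMP1, had a log2 fold change of -1.07.

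Among markers of early lineages, primitive endoderm genes rose and those of other lineages were mixed. Of 23 primitive endoderm genes, 15 rose, 3 fell and 5 were not called (camera adjusted p = 0.0035; adjusted p = 0.23 with an estimated correlation). Gata4 rose from 1.80 ± 0.188 to 6.11 ± 0.419 CPM (log2 fold change 1.74, SE 0.168, edgeR adjusted p = 7.1e-08), Pdgfra rose by 1.98, and the matrix gene Sparc rose by 0.55 on the log2 scale. Of 25 trophoblast genes, 10 fell, 5 rose and 10 were not called (camera adjusted p = 0.0079; adjusted p = 0.21 with an estimated correlation, and 0.098 with limma voom). Fgfr2 and Tfap2c had log2 fold changes of -1.67 and -0.97. Cdx2, the trophectoderm regulator, lay near the floor at 0.324 ± 0.0644 against 0.929 ± 0.0959 CPM (log2 fold change -1.54, SE 0.371, edgeR adjusted p = 0.0019). Of 17 gastrulation and mesoderm genes, 7 rose, 6 fell and 4 were not called (camera adjusted p = 0.98). Its members T and Fgf8 had log2 fold changes of -2.55 and -2.26. Of 14 neural genes, 6 fell, 4 rose and 4 were not called (camera adjusted p = 0.042; adjusted p = 0.21 with an estimated correlation). The neurofilament gene Nefl fell from 25.9 ± 1.43 to 13.1 ± 1.10 CPM, Nes and Olig2 had log2 fold changes of -0.77 and -0.59, and the neural list call was lost in 5 further alternatives. Gata2, a regulator of blood and trophoblast genes that published work on these cells names, was at 13.8 ± 1.16 CPM in the knockout and 14.9 ± 0.597 CPM in the wild-type lines (log2 fold change -0.10, SE 0.096, edgeR adjusted p = 0.39). With library GC trends removed, an alternative chosen after the data were seen, it was called lower (log2 fold change -0.24, adjusted p = 0.036). Of 14 GATA2 target and GATA-associated genes, 5 rose, 2 fell and 7 were not called (camera adjusted p = 0.4). Dab2, the X-linked Gata1 and Zfpm1 rose by 1.04, 1.49 and 0.95. Gata1 lies at 5 to 10 Mb on the X, where genes above 5 CPM had a median log2 fold change of 1.55.

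Targets of p53 rose as a group, while the reported miR-34a targets went both ways. Of 29 p53 target genes, 21 rose, 0 fell and 8 were not called (camera adjusted p = 1.6e-06; adjusted p = 0.07 with an estimated correlation). The pro-apoptotic gene Pmaip1 rose from 37.5 ± 1.81 to 87.4 ± 1.60 CPM (log2 fold change 1.23, SE 0.062, edgeR adjusted p = 6.6e-12), and the antiproliferative gene Btg2 and the stress gene Sesn2 rose by 0.87 and 0.71. Of 48 reported miR-34a target genes, 18 rose, 16 fell and 14 were not called (camera adjusted p = 0.69). The median log2 fold change of these targets was -0.04. Among them the AP-1 gene Fosl1 rose by 1.42, and Mycn and Lef1 had log2 fold changes of -0.93 and -1.40. Of 26 hypoxia and glycolysis genes, 10 rose, 2 fell and 14 were not called (camera adjusted p = 0.15), with Pfkp and Vegfa higher by 0.99 and 0.77 and Pdk1 at -0.73. Of 18 interferon response genes, 3 rose, 6 fell and 9 were not called (camera adjusted p = 0.61), with a median of 0.09 and a mean of -0.06. Oas1a rose by 1.45, and Ddx58 and Bst2 had -0.39 and -0.38. Of 13 histone genes, 6 rose, 1 fell and 6 were not called (camera adjusted p = 0.23), with Hist1h4c and Hist1h3c at 1.90 and 1.17 and Hist1h1c at -0.65. Of 12 mitochondrially encoded genes, 1 fell and 11 were not called (camera adjusted p = 0.023; adjusted p = 0.54 with an estimated correlation, and 0.08 with library GC trends removed). The member that fell, mt-Nd4, had a log2 fold change of -0.64, and mt-Nd5 and mt-Nd6 had -0.57 and -0.81 (edgeR adjusted p = 0.051 and 0.079). Without wild-type replicate 1 the adjusted p of mt-Nd4 was 0.077. Of 37 retroviral silencing and chromatin repressor genes, 15 fell, 6 rose and 16 were not called (camera adjusted p = 0.031; adjusted p = 0.33 with an estimated correlation, and 0.086 with library GC trends removed). The X-inactivation factor Smchd1 had a log2 fold change of -0.83, and the X-linked histone methyltransferase gene Suv39h1 rose by 1.37. Suv39h1 lies at 5 to 10 Mb on the X, where 34 of 35 genes above 5 CPM were called higher, with a median of 1.55.

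**Figure D2:**
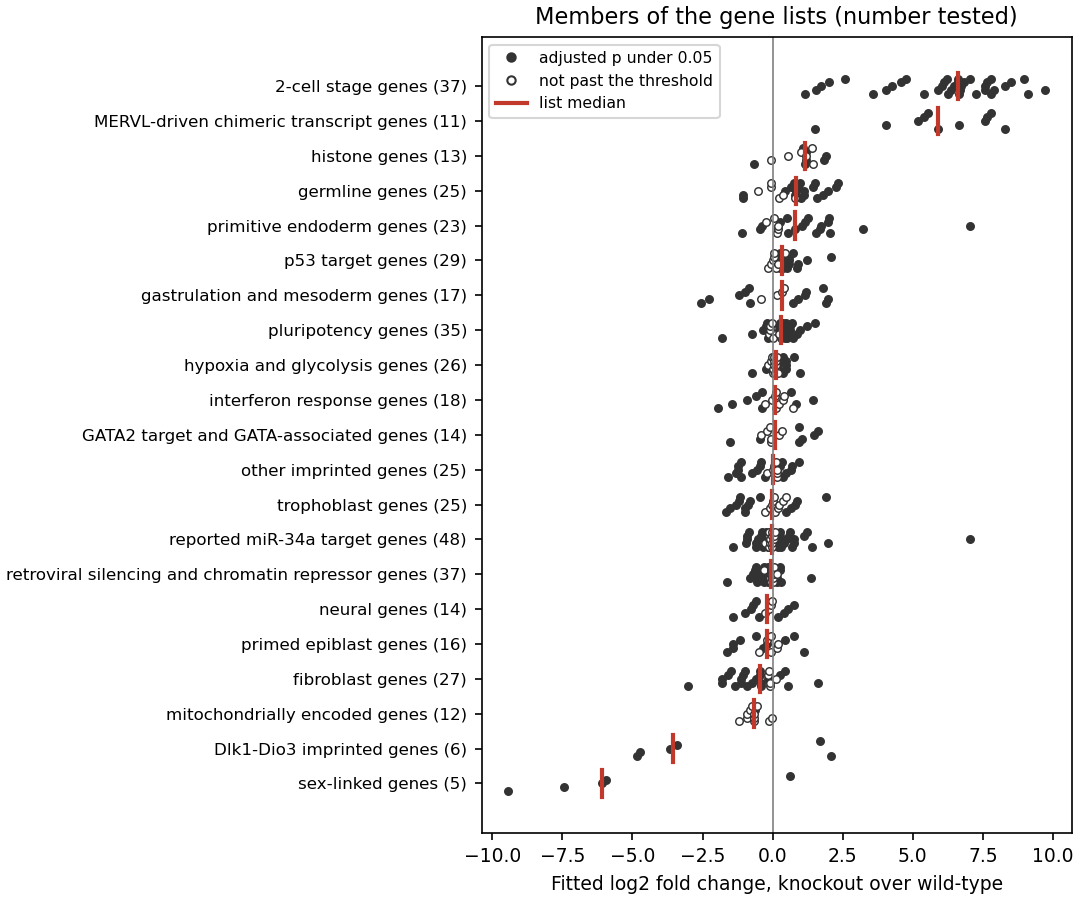
Fitted log2 fold change of each tested member of 21 gene lists, knockout over wild-type, from 3 libraries per genotype. Filled points passed adjusted p 0.05, open points did not, and red lines are list medians, which run from -6.08 for the sex-linked genes to 6.61 for the 2-cell stage genes. Values of genes with 3 or fewer counts in a group depend on the prior count.

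Fibroblast genes, which feeder cells or residual fibroblasts would bring, moved with genotype. Of 27 tested, 18 fell, 4 rose and 5 were not called (camera adjusted p = 3.3e-07; adjusted p = 0.23 with an estimated correlation). The smooth muscle genes Tagln and Acta2 fell from 164 ± 7.95 to 46.6 ± 0.902 and from 161 ± 18.9 to 45.6 ± 1.12 CPM (both log2 fold changes -1.81), and S100a4 rose by 1.62. Of 6 members named after their values were seen, Postn fell from 15.8 to 2.05 CPM (log2 fold change -3.03, edgeR adjusted p = 6.0e-11), Tnc from 229 to 76.4 CPM (log2 fold change -1.58) and Col1a1 from 254 to 127 CPM (log2 fold change -0.99, edgeR adjusted p = 0.014) and Vim rose by 0.44, while Fn1 and Col1a2 had log2 fold changes of -0.08 and -0.10 (edgeR adjusted p = 0.21 and 0.68).

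Imprinted noncoding RNAs of the Dlk1-Dio3 region on chromosome 12 were lower in all 3 knockout libraries than in any wild-type library. Rian (ENSMUSG00000097451, 109603940 to 109661716) fell from 70.8 ± 1.89 to 2.61 ± 0.543 CPM (log2 fold change -4.86, SE 0.102, edgeR adjusted p = 2.5e-17). Meg3 (ENSMUSG00000021268, 109541001 to 109571726) fell from 93.5 ± 16.5 to 7.12 ± 0.780 CPM (log2 fold change -3.67, SE 0.151, edgeR adjusted p = 1.3e-07). Mirg fell from 8.13 ± 1.30 to 0.315 ± 0.216 CPM and Rtl1 from 3.10 ± 0.387 to 0.240 ± 0.139 CPM, with log2 fold changes of -4.72 and -3.42. A transcript antisense to Rtl1 is known, and the strand setting of the counting was not given. Dlk1 and Dio3 rose by 1.69 and 2.09, so that 4 of the 6 genes fell and 2 rose (camera adjusted p = 1.0e-09; adjusted p = 0.07 with an estimated correlation, and 0.073 with limma voom). Of 25 other imprinted genes, 11 fell, 7 rose and 7 were not called (camera adjusted p = 0.0035, downward; adjusted p = 0.1 with an estimated correlation, and 0.093 with limma voom), although the median was 0.01 and the mean -0.23. Peg3 fell from 486 ± 45.7 to 162 ± 5.59 CPM (log2 fold change -1.59), and Sfmbt2 and Mest had -1.23 and -1.14.

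The genotypes also differed in sex-linked expression, and the labels give no sex for the lines. The 4 Y-linked genes of the sex-linked list had 1 to 10 counts together in a knockout library and 329 to 977 in a wild-type library. Ddx3y and Kdm5d fell by log2 fold changes of -5.95 and -6.08. Eif2s3y had 1 count in the knockout and 832 in the wild-type libraries, a ratio of 970.0 (173.6 to 38357.4), and Uty had 1 and 212, a ratio of 247.2 (43.9 to 9807.6). Uba1y had 0 and 94 and was at least 36.5-fold lower in the knockout. Xist, the noncoding RNA of X inactivation, was low in both genotypes, at 4.90 ± 0.749 and 3.06 ± 0.082 CPM (log2 fold change 0.62, SE 0.163, edgeR adjusted p = 0.0037). The sex-linked list had a camera adjusted p of 7.6e-15, with adjusted p = 0.07 with an estimated correlation. The 327 X-linked genes above 5 CPM had a median log2 fold change of 0.37, while medians of the autosomes ran from -0.12 to 0.02. The genotype comparison thus cannot be separated from this difference in sex chromosome expression for any gene described here. Adjusted over the list alone, counts of higher and lower genes equalled those over all genes in each list except 5. These were 8 and 6 for gastrulation and mesoderm, 18 and 3 for germline, 7 and 1 for histone, 6 and 10 for trophoblast, and 0 and 0 for mitochondrially encoded genes.

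**Figure D3:**
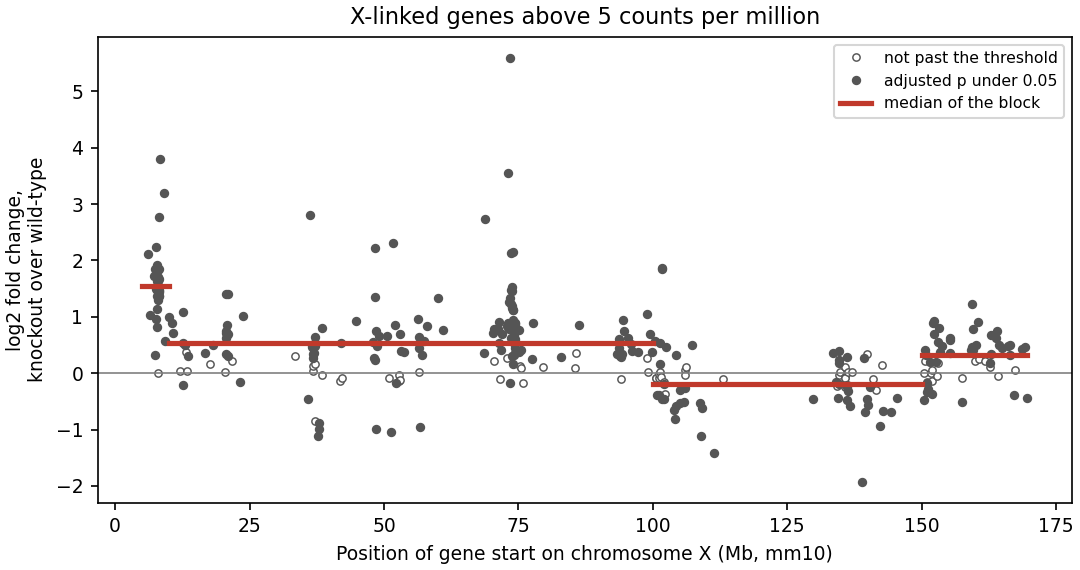
Log2 fold change, knockout over wild-type, of the 327 X-linked genes above 5 CPM against the start of the gene on chromosome X in Mb (mm10). Filled points passed adjusted p 0.05, and red lines are medians of 4 blocks drawn after the data were seen. The median was 1.55 at 5 to 10 Mb, 0.53 at 10 to 100 Mb, -0.19 at 100 to 150 Mb and 0.33 beyond.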

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

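The alternatives with autosomal genes only, with genes and repeat families in 1 fit, with library GC trends removed and with repeat counts scaled alone were chosen after the data were seen, as were all alternatives for the 2-fold counts and the repeat families. Over all alternatives run, 3077 to 4146 genes were higher and 2841 to 3948 lower in the knockout, and 851 to 1586 were higher and 321 to 578 lower by at least 2-fold, each within 1.5 times the reported count. Leaving out 1 library gave 3274 to 4146 higher and 2844 to 3838 lower genes. With library GC trends removed 3728 genes were higher and 3376 lower, and 6044 of those calls were shared with the 7433 reported. The median log2 fold change of all genes stayed between -0.005 and 0.016 over the settings. Higher repeat families numbered 38 to 58 with 1 library left out and 77 with genes and families in 1 fit, and 85 were higher and 61 lower with repeat counts scaled alone, so the balance of directions turned. Lower repeat families numbered 110 with genes and families in 1 fit, and 26 to 79 with 1 library left out, with the lowest count, 26, without knockout replicate 1 and 47 without wild-type replicate 1. The cause was not tested. Of the 21 lists, 15 passed with the preset correlation and 0 with an estimated one, and why the calls ended was not tested. The neural list, adjusted p = 0.042, lost its call with limma voom (0.098), with at least 1 CPM in 3 samples (0.054), with the block (0.054), without knockout replicate 3 (0.062) and without wild-type replicate 1 (0.069). The histone list was past the threshold with DESeq2 (0.04) and without knockout replicate 1 (0.034), and the hypoxia and glycolysis list with DESeq2 (0.016) and limma voom (0.038). The test of the gastrulation and mesoderm list, never past the threshold, turned downward with medians of 0.38 with DESeq2, 0.35 with no filter, 0.24 with at least 1 CPM in 3 samples, 0.38 with the block and 0.21 with GC trends removed, and in 3 of the fits without 1 library (medians over the 6 such fits 0.24 to 0.47). Named genes held their direction in every alternative, and apart from Gata2 and mt-Nd4 only mt-Nd5 and mt-Nd6 changed sides of the threshold, in 6 and 4 alternatives. The labels speak of 3 pairs without saying that the number marks the pair. Same-numbered libraries had correlations of deviations of 0.27, -0.02 and 0.24, so the numbers were not taken to pair the samples, and not every library correlated best with its own number. With the replicate number as a block, 4055 genes were higher and 3779 lower, 1100 and 394 by at least 2-fold, 61 and 88 repeat families were called, and 14 lists passed. The fits with the first run only and the second run only, and the comparison of the runs, were not run, because the columns of the second run match no label. Depth limits genes near 0 counts, whose folds are bounds.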

Other observations

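All tests of explanations in this part were chosen after the results were seen. The Padi, Wnt and Oas genes were picked after their values were seen and were not tested as sets, while 7433 of all 14717 tested genes were called. Wnt3, Oas1a, Oas2 and Oasl2 are also members of the gene lists. All 5 tested Padi genes, peptidylarginine deiminases clustered on chromosome 4, rose, with log2 fold changes from 1.02 for Padi4 to 3.14 for Padi1, and Padi3 rose from 3.13 to 13.6 CPM. Of 12 tested Wnt genes, 7 fell and 2 rose. Wnt7b fell from 45.3 to 14.7 CPM (log2 fold change -1.60, edgeR adjusted p = 8.2e-12), and Wnt8a and Wnt3a had -1.96 and -1.62, while Wnt6 and Wnt10a rose by 1.56 and 1.45. Of 7 tested Oas genes, antiviral oligoadenylate synthetases, 6 rose, led by Oas1c at 1.85, and Oasl2 had -0.91.

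The genes next to the deleted microRNA were higher in the knockout. Gpr157 (chromosome 4, 150087365 to 150105927), 18.8 kb away, rose from 0.917 to 8.52 CPM (log2 fold change 3.23, edgeR adjusted p = 3.3e-11), and the noncoding gene Gm13067, 11.5 kb away on the other side, rose from 1.10 to 8.64 CPM (log2 fold change 2.99, edgeR adjusted p = 4.0e-10). Of 11 other tested genes within 500 kb, 4 rose, 2 fell and 5 were not called. The largest of these changes were in Car6 and Slc2a7, at under 2 CPM, which rose by 1.38 and 1.14.

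The first pattern weighed is the rise of the 2-cell stage genes. The 11 members with at least 80% unique 50-base stretches were all called higher. Their median log2 fold change was 3.10 when genes near 0 counts were set to their bounds. Most of them needed the knockout libraries to pass the count filter, which largely fixed their direction. Calcoco2, Cyp2b23 and Ddit4l, with wild-type means of 0.993 CPM or more, rose by 1.16, 1.71 and 1.56. For these 11, the values argue against reads shared with other annotated transcripts. Copies outside annotated transcripts were not checked, and sharing stays open for the other members. A general release of retroviral repeats is also argued against, because 202 IAP, ETn, MMETn and RLTR families had a median of -0.04 (quartiles -0.26 and 0.23), and 301 families, with ERVB, RMER and other retroviral names added, had a median of -0.01 (quartiles -0.20 and 0.22). A release of single families beside MERVL stays open, since 5 of the 301 rose by at least 2-fold, ERVB4_2-LTR_MM the most at 3.01. The sex chromosome difference between the lines cannot be told apart from genotype, since 0 of the 3 knockout libraries reached 0.5 of the lowest wild-type level of the 4 Y-linked genes. The measure first used, the sum over all genes annotated on Y, gave 3 of 3 knockout libraries, which would have argued against this explanation, and it was replaced after that result was seen because the gene model Gm47283, with 655 to 2567 counts in every library, held 99.0% of those counts in the knockout. Loss of miR-34a therefore remains an open hypothesis beside it.

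The second pattern is the shape of the X-linked difference. Loss of the Y chromosome alone would leave the X unchanged, but the X median was 0.37 against at most 0.02 on an autosome. The block at 100 to 150 Mb was drawn after its 73 genes were seen to be low, with a median of -0.19, so a search along every chromosome for the run of 73 neighbouring genes lowest against its rest was made. On the X it lay 0.73 below the rest (difference -0.73), against -0.27 at most on the 19 autosomes, and 0 of 1000 shuffles of the X gene order were as low. Medians of 5 windows of equal gene number along the X ran from -0.11 to 1.02. These values argue against a second active copy of the whole X with an even effect along it. GC content does not account for the block at 5 to 10 Mb, where 34 of 35 genes were called higher and the median was 1.55, and 1.5 with library GC trends removed. All 3 knockout libraries shared this profile, so knockout lines of 1 origin cannot be told apart from a regional effect shared by independent lines. Partial reactivation and a partial gain of an X chromosome were not tested. A partial gain may be looked for in DNA, where copy number would not show reactivation.

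The third pattern is the low level of Meg3, Rian and Mirg. Fibroblasts express these RNAs, so fewer feeder fibroblasts in the knockout libraries could lower them. The 27 tested members of the fibroblast list had a median log2 fold change of -0.46 (quartiles -1.13 and -0.12). The values were -3.67 for Meg3, -4.86 for Rian and -4.72 for Mirg. The largest fall was in Postn at -3.03, and 0 members fell by as much as Meg3. The 18 members under the wild-type level of Meg3 had a median of -0.53. How much of each member's level comes from the iPSCs themselves was not measured, and such expression would hide a loss of fibroblasts. These medians therefore cannot decide the question. Fewer fibroblasts stay open as part or whole of the cause, and 18 of the 27 fell. Silencing within the imprinted cluster during reprogramming, known in mouse iPSC lines, is a candidate explanation that was not tested. Dlk1 and Dio3 of the same cluster rose by log2 fold changes of 1.69 and 2.09, and these rises were not used to weigh silencing.

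The 6 libraries can be split into 3 and 3 in 10 ways, so no share under 0.1 can be had. The real split called 7433 genes, 1515 of them by at least 2-fold, and 130 repeat families, each the highest of the splits (1 of 10). The other 9 called 0 at most with edgeR, with 34 to 466 genes and 7 to 46 families at unadjusted p under 0.05. Each of those 9 puts 2 libraries of one genotype with 1 of the other, so the genotype difference widens the spread inside its groups. Few calls follow from that mixing, so the 0 is no baseline for the calls of the real split. With camera at the preset correlation the real split called 15 lists, and the other splits called 6 to 9. Lists were thus called even where the groups mixed the genotypes. A list call at that correlation therefore does not by itself mark the genotype.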
